A study of Sebastes melanops with 3 samples.

How the data were processed

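Testis cells of adult black rockfish, labelled Sebastes melanops, were profiled by droplet single-cell RNA sequencing in 3 libraries. The sample titles give 1 library for each of 3 stages of the yearly reproductive cycle, named regressed, regenerating and differentiating. Per the labels' protocols, the testis was freed of its outer coat, digested with collagenase, trypsin and DNase, strained, washed by repeated spins and loaded as a suspension on a 10x Chromium controller with reagents that count the 3′ ends of transcripts. No sort or gate is stated. How many fish went into a library is not given in the sources used here.

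The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. Per the submitters' processing notes, Cell Ranger 2.20 and STAR were used, with no role or setting stated for either. Whether the reagent chemistry and the software version were the same for all 3 libraries could not be settled from the files, and a difference in either would change UMIs and genes per cell. The genome build, the annotation and the rule that called barcodes as cells are not given in the sources used here. The lowest total of any deposited barcode was 500 UMIs in every library, so barcodes below that level had been removed before deposit and a minimum of 500 UMIs took out nothing more. The authors' feature lists give 24094 gene identifiers, each paired with the same identifier plus a suffix and with no symbol. Genomic positions of these genes are not given in the sources used here. None of the symbols in the 17 marker lists and 26 gene lists fixed in advance was matched (0 found). Cell classes therefore stayed unnamed, the gene lists and the cell cycle measures were not analysed here, and mitochondrial genes could not be used as a filter.

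Barcodes with at least 500 UMIs and 200 genes were kept, which removed 895 of 7872 barcodes in the regressed library, 824 of 9203 in the regenerating library and 459 of 6385 in the differentiating library. Doublets were called per library with Scrublet in scanpy 1.11.5 and removed. The caller marked 180 barcodes (2.58%), 401 (4.79%) and 187 (3.16%) in the same order. This left 20514 cells. Counts per 10000 were log-transformed, 2000 variable genes were chosen with the library as batch key, and 40 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2) were computed over all 3 libraries together without integration. Clusters were numbered by size.

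The 32 clusters were joined into families, A to H, by average linkage on the correlation of their centred log2(CPM + 10) profiles over the 7650 genes with more than 500 UMIs, where CPM is UMIs scaled to a total of 1000000 per sum. Clusters were joined down to a mean correlation of 0.4. This grouping was chosen after seeing the data. A family is a group of clusters with related profiles and does not stand for a named cell type.

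For each comparison the UMIs of kept cells were summed per library or per family and library, scaled to CPM and compared as log2 of the ratio of CPM + 10, over genes with at least 20 UMIs in the 2 sums. Families were compared where both libraries held at least 50 of their cells. The spread of log2 ratios is their SD across genes, and it is set beside the SD that counting error alone gives. Correlations are across genes, which are not independent replicates. With 1 library per stage no test was made and no p-value, standard error or number of changed genes is given. Shares carry exact Clopper-Pearson 95% intervals and ratios carry exact conditional binomial 95% intervals. These cover counting error only, not the spread between fish, and a stage cannot be told apart from its library. Where a count was 0, the limit is 3 counts of the total. Genes per cell were compared after thinning each cell to 1000 UMIs, which left out 648 regressed, 947 regenerating and 1172 differentiating cells.

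The rule for named genes, set before the data were examined, allowed at most 2 identifiers that rose and 2 that fell where no symbols are paired with them. They are the genes with the highest and the lowest log2 ratio among those with at least 100 UMIs in the 2 libraries, in each of the 2 successive steps of the cycle. The choice of these steps was made after the lack of symbols was known and before the ratios were computed.

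The ratios and the clustering were tested on simulated data. Counts were drawn from 1 profile pooled over the 2 libraries compared, with 200 genes changed by known folds. The intervals held the true ratio for 95.5% of changed genes in regenerating against regressed (17103 genes). The shares were 94.5% in differentiating against regenerating (16926 genes) and 95.0% in differentiating against regressed (16789 genes). Draws and intervals both assume counting error alone, so this coverage is built in and says nothing of the spread between cells. The added 10 CPM draws ratios of low genes toward 0. A true log2 ratio of 2 came back with a median of 1.26, 1.29 and 1.32 in those comparisons, and one of -2 with a median of -0.69, -0.72 and -0.91, so falls are understated more than rises. Clustering of 6000 simulated cells over 24094 genes gave an adjusted Rand index of 0.86 for single clusters. These cells were drawn with counting error alone from the profiles of the clusters found here. Each new cluster took the true family of most of its cells, and 100% of cells then lay in their true family. The joining of clusters into families was not run on simulated cells, so this share does not test it.

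Alternatives set in advance were all deposited barcodes kept, at least 1000 UMIs and 500 genes, doublets kept, Leiden resolutions 0.5 and 2.0, each library clustered alone, TMM factors (edgeR 4.0.16), the mean over cells of each cell's CPM, CPM + 1, no minimum of UMIs, and thinning to 500 UMIs. New clusters took the family that most of their cells had in the main clustering. Joining families at 0.3 or 0.5, and profiles over the 2000 variable genes, were added after seeing the data.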

Results

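Dissociated testis cells of black rockfish were sequenced from 1 library each at the regressed, regenerating and differentiating stages, to follow the cell makeup of the testis through its yearly cycle. The deposited matrices held 31499459 UMIs over 7872 barcodes for the regressed library, 35216381 over 9203 for the regenerating library and 27122106 over 6385 for the differentiating library. After filtering, 6797, 7978 and 5739 cells remained, with medians of 2692, 2624 and 3114 UMIs and of 619, 515 and 1160 genes per cell. Thinned to 1000 UMIs per cell, the medians were 344, 410 and 575 genes. The 50 most abundant genes took 43.7% of UMIs in the regressed library, 46.0% in the regenerating library and 23.0% in the differentiating library. There are no replicates, so every comparison is of libraries and its intervals cover counting error alone.

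Cells fell into 32 clusters that joined into 8 families by their expression profiles. Family A held 31.2% of all cells, family B 29.2%, family C 15.3%, and families D to H between 7.24% and 2.45% each. The families differed in how many genes their cells used. At 1000 UMIs the median was 609 genes in family C, 485 in family A, 383 in family E and 247 in family B. In family G, which is cluster 12 alone, 12 genes took 55.5% of all UMIs and the median cell held 727 UMIs. In family C, 121 genes stood at 200 CPM or more and at least 16-fold above the next family, and no gene passed that bar in family A. Of the 32 clusters, 18 had at least 90% of their cells from 1 library, and these held 75.5% of all cells. A cluster of this kind may be a library rather than a cell type.

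Family makeup differed widely between the 3 libraries. The regressed library was a mixture led by family B, with 42.2% of cells (95% interval 41.0 to 43.4%), a place that rests on how clusters were joined (4.08% when joined at 0.5), followed by family E at 19.8% (18.9 to 20.8%), family D at 14.3% (13.5 to 15.1%), family F at 10.5% (9.77 to 11.2%) and family A at 8.42% (7.77 to 9.10%). In the regenerating library, family A made up 52.5% (51.4 to 53.6%) and family B 38.8% (37.8 to 39.9%). In the differentiating library, family C made up 53.2% (51.9 to 54.5%), family A 28.6% (27.4 to 29.8%), family G 10.5% (9.73 to 11.3%) and family H 6.01% (5.41 to 6.66%).

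**Figure D1:**
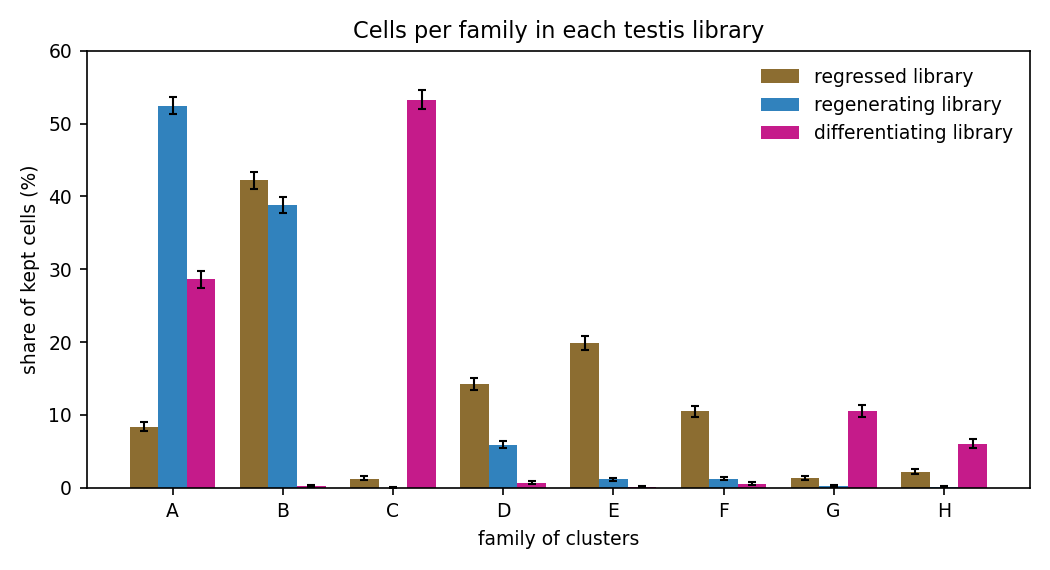
Share of kept cells (%, vertical axis) in each family of clusters (horizontal axis) for the regressed, regenerating and differentiating libraries, 1 library each. Error bars are exact 95% intervals for counting error, and family C reaches 53.2% in the differentiating library against 1.28% and 0% in the others.

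Between the regressed and the regenerating library, family A went from 8.42% to 52.5% of cells and from 33.4% to 73.7% of UMIs. Families E, F and D were smaller in the regenerating library, with 1.15% (0.931 to 1.41%), 1.28% (1.04 to 1.55%) and 5.94% (5.43 to 6.48%) of cells. Family B stood at 42.2% and 38.8% of cells, in different clusters, and at 4.08% and 36.9% when families were joined at a correlation of 0.5. Cluster 5, with 15.9% of regressed cells, had none of 7978 regenerating cells, which allows a share of up to 0.0376%. Cluster 6 went from 15.4% to 0.0877%, and cluster 2 went from 0.191% to 19.7%. Cells of family B in the regenerating library had few genes, with a median of 308 against 704.5 in the regressed library. Part of this gap goes with depth (median 1871.5 against 3221 UMIs), and thinned to 1000 UMIs the medians were 215 and 328 genes. With at least 1000 UMIs and 500 genes required, regenerating cells were 93.0% family A and 5.83% family B, with 0.637% in family D, 0.484% in family F and 0% in family E, and family F stood at 2.78% of regressed cells.

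Across 17142 genes the regenerating and regressed sums had a Spearman correlation of 0.85, and their log2 ratios had an SD of 0.55, against 0.04 from counting error. With CPM + 1 in place of CPM + 10 the SD was 0.95. The gene with the highest log2 ratio was Ssc_10002076, which went from 7.63 CPM (225 UMIs) in the regressed library to 164 CPM (5252 UMIs) in the regenerating library, a ratio of 21.5 (18.8 to 24.7) and a log2 ratio of 3.31. Of its regenerating UMIs, 95.6% lay in family A, where it went from 17.7 to 213 CPM, and in cluster 11, shared by both libraries, it went from 59.8 to 668 CPM. It had a UMI in 43.5% of regenerating and 16.4% of regressed cells of family A, although the regressed cells were deeper (median 16997 against 5182 UMIs). In family B, at medians of 1871.5 and 3221 UMIs, these shares were 5.23% and 0.837%.

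The gene with the lowest log2 ratio over this step was Ssc_10006353, which went from 973 CPM (28711 UMIs) to 1.28 CPM (41 UMIs), a 759-fold difference (559 to 1058). Family E held 95.4% of its UMIs in the regressed library. Its level there was 8873 CPM, with a UMI in 84.8% of cells. In the 92 regenerating cells of family E it stood at 127 CPM, with a UMI in 17.4% of cells at a median of 1978 UMIs. Family E was mostly cluster 7 in the regressed (75.6%) and cluster 18 in the regenerating library (97.8%). Inside cluster 18 alone the level was 13470 CPM in 300 regressed cells and 123 CPM in 90 regenerating cells. In regressed cells of family D, with a median of 3347 UMIs, 8.24% had a UMI of this gene.

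Between the regenerating and the differentiating library, the leading family changed from A to C and family B stood below 1% of cells. Family C went from 0 of 7978 cells, which allows a share of up to 0.0376%, to 3056 of 5739 cells. Family B went from 38.8% to 0.244% (0.133 to 0.409%), or 14 cells, none of which had a UMI of Ssc_10021848, the leading transcript of the family elsewhere. Family G went from 0.201% (0.115 to 0.326%) to 10.5%, and family H from 0.113% (9 cells, 0.0516 to 0.214%) to 6.01%. The former value of family H ran from 0% with each library clustered alone to 0.196% with all barcodes kept. Family A went from 52.5% to 28.6%, and here too the clusters changed. Cluster 1, with 34.1% of regenerating cells, had 0.662% of differentiating cells, while clusters 8 and 14 had 16.8% and 10.2% of differentiating cells against 0.251% and 0.0125% of regenerating cells. When families were joined at a correlation of 0.5, clusters 8 and 14 left family A, whose differentiating share was then 1.66%.

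The all-cell profiles of these libraries were further apart than those of the previous step. Over 16981 genes the Spearman correlation was 0.66 and the SD of log2 ratios 1.03, against 0.05 from counting error. With CPM + 1 the SD was 1.68. Ssc_10008054 had the highest log2 ratio and went from 2.03 CPM (65 UMIs) to 3252 CPM (83166 UMIs), a ratio of 1599 (1254 to 2072). Family C held 99.1% of its differentiating UMIs, at 6132 CPM, with a UMI in 85.8% of cells. Inside the family it stood at 751 CPM in cluster 4, where 63.6% of cells had a UMI, and at 10763, 10147 and 6069 CPM in clusters 3, 20 and 24. In other differentiating cells the share with a UMI was 22.0% in family A (median 4947.5 UMIs), 20.2% in family G (median 722 UMIs) and 18.8% in family H (median 1627 UMIs).

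Ssc_10021848 had the lowest log2 ratio and went from 49577 to 524 CPM, a 94.7-fold difference (93.1 to 96.3). It was the leading transcript of family B, at 200020 CPM in regenerating and 104099 CPM in regressed cells of that family. It was not particular to family B, since it also led regenerating families D, E and F, at 84696, 94953 and 62352 CPM. It took 51916 CPM of the whole regressed library. A UMI of it was also found in 98.1% of regenerating cells of family A, at 4613 CPM, so the share of cells with a UMI does not mark its source in that library. Regressed shares were 98.8% in family A, 93.1% in family C and 88.9% in family G, so the same limit holds there. In the differentiating library, family H held 73.7% of the UMIs of this gene at 14239 CPM, and 5.01% of cells in family C had a UMI.

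**Figure D2:**
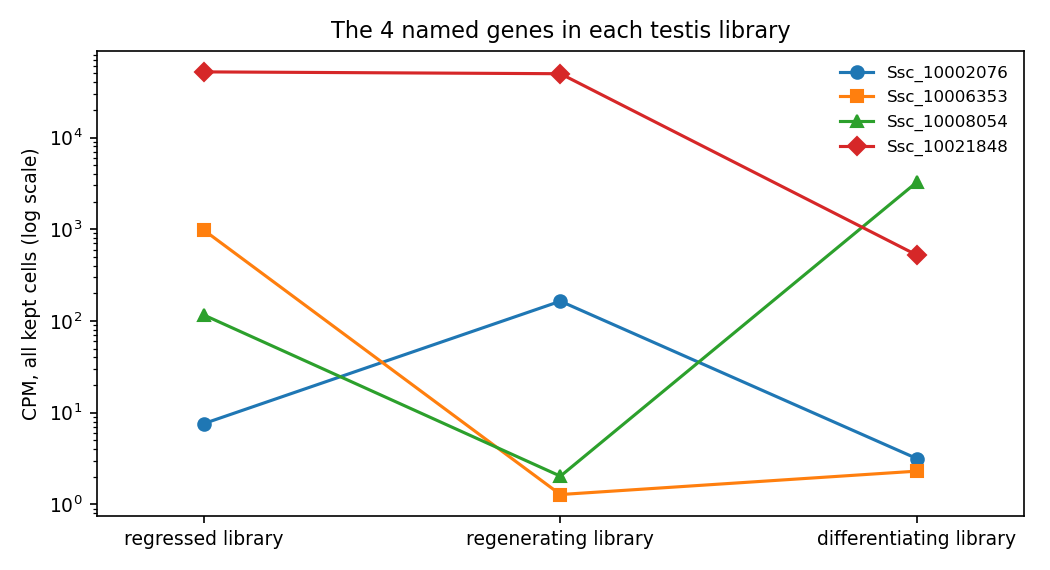
CPM over all kept cells (vertical axis, log scale) of the 4 named genes in the regressed, regenerating and differentiating libraries (horizontal axis), 1 library per point; lines join the points of a gene. Ssc_10008054 goes from 2.03 in the regenerating to 3252 in the differentiating library, and Ssc_10021848 from 49577 to 524.

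The differentiating and regressed libraries, at the ends of the series, differed in nearly every family. Families B, D, E and F together made up most regressed cells, and in the differentiating library they stood at 0.244%, 0.697% (0.498 to 0.948%), 0.139% (0.0602 to 0.274%) and 0.540% (0.367 to 0.766%). Family C was present in the regressed library with 87 cells, 1.28% (1.03 to 1.58%), all of them in cluster 3. Clusters 4, 20 and 24, the other parts of family C, had 0 of 6797 regressed cells each, which allows up to 0.0441%. Families G and H were both larger in the differentiating library, at 10.5% against 1.32% (1.07 to 1.63%) and 6.01% against 2.18% (1.84 to 2.55%). The share of family G depends on the 200-gene minimum and on the clustering. At resolution 0.5 it was 2.42% of regenerating cells, and with each library clustered alone it was 0% of regenerating and 2.38% of regressed cells. With all deposited barcodes kept it was 10.8% in the regressed, 3.36% in the regenerating and 16.6% in the differentiating library. With at least 1000 UMIs and 500 genes it was 0% in every library, family H stood at 1.12% of differentiating and 1.28% of regressed cells, the opposite order, and family D at 1.31% of differentiating cells. Other settings put family D lower there, at 0.407% with all barcodes, 0.422% with doublets kept and 0.436% at resolution 0.5. Family E stood at 0% of differentiating cells with each library clustered alone, and family F at 0.304% with at least 1000 UMIs and 500 genes. Family A was larger in the differentiating than in the regressed library at 28.6% against 8.42%, an order that turned, 1.66% against 8.11%, when families were joined at 0.5.

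Over 16848 genes these end libraries had a Spearman correlation of 0.64 and an SD of log2 ratios of 1.09, against 0.05 from counting error and 1.78 with CPM + 1. A mixture of the 8 family profiles, weighted by each library's share of UMIs per family, accounted for 89.4% of the variance of these log2 ratios. The same mixture accounted for 82.2% between differentiating and regenerating and 60.4% between regenerating and regressed. Families held mainly by 1 library carry that library's own profile into the mixture, which can raise these percentages. Changes of clusters within a family are left out of the mixture, which can lower them. The part of cell makeup may therefore be above or below these values.

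Within families, expression also differed between libraries, although the clusters that made up a family often differed too. RNA free in the suspension was not taken off, so transcripts abundant in a library may enter the sums of all its families and clusters. Ssc_10021848, for example, stood at 3689 CPM in regressed and 16.2 CPM in differentiating cells of family C. How much free RNA adds to the spreads within families and clusters was not tested. Family A was the only family with at least 50 cells in all 3 libraries. Its regenerating and regressed cells were close, with an SD of log2 ratios of 0.37 over 15469 genes (0.07 from counting error) and a Spearman correlation of 0.92. Differentiating cells of family A stood further off, with SDs of 0.68 against regenerating and 0.70 against regressed cells, and correlations of 0.75 and 0.71. Different clusters led the family in each library. Cluster 17 held 67.7% of its regressed cells, cluster 1 held 65.0% of its regenerating cells and cluster 8 held 58.6% of its differentiating cells. Clusters 8 and 14, which held most of its differentiating cells, left the family when families were joined at 0.5. The gap of the differentiating cells therefore rests on the join at 0.4.

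Between the regenerating and regressed libraries the SD was 0.65 in family B, 0.96 in family D, 0.87 in family E and 1.21 in family F, against 0.09, 0.21, 0.48 and 0.37 from counting error. Here too other clusters led each family in each library. Cluster 16 held 99.6% of regenerating and cluster 9 held 93.2% of regressed cells of family D, and in family F these were cluster 29 with 77.5% and cluster 13 with 91.2%. Inside single clusters that both libraries shared, the SD was 0.50 in cluster 11 (family A), 0.84, 1.03 and 1.49 in clusters 10, 22 and 26 (family B), 0.95 in cluster 16 (family D) and 1.18 in cluster 18 (family E), against 0.20, 0.32, 0.35, 0.42, 0.36 and 0.45 from counting error. The median log2 ratio of all genes, regenerating against regressed, was -0.29 in family B, -0.63 in family D, -0.80 in family E and lower still in family F. Between the differentiating and regressed libraries the SD was 0.99 in family C, 1.17 in family G and 0.92 in family H, against 0.38, 0.57 and 0.33 from counting error, and the median log2 ratios were 0.28, 0.55 and 0.46. Single genes are to be read with these medians in view, but in families B to H each median lay on the side of the larger UMI sum. Genes enter by their UMIs over both sums, so depth may shape the medians, which are no baseline for abundant genes. For scale, pairs of different families inside 1 library had a median SD of 1.24 in the regressed, 0.96 in the regenerating and 1.46 in the differentiating library. The gaps between libraries within families A and B were smaller than every pair of families in the regressed library. The closest of these pairs, B and E, was at 0.73. Inside the shared clusters 10, 22 and 26 of family B the SD was above that. In families C to H the gaps were above 0.73 with counting error included. In family E, with 92 regenerating cells, that error is too large for the order to be read. The gaps of families C and H, 0.99 and 0.92, were still below the closest pair in the differentiating library, A and G at 0.998. These SDs rest on unlike gene sets, from 15469 genes in family A to 1481 in family G, so their order does not compare like with like.

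Cells of the same family also differed in depth. Family A had a median of 16997 UMIs per cell in the regressed library, 5182 in the regenerating and 4947.5 in the differentiating library. Family B had 3221 and 1871.5 in the regressed and regenerating libraries, and family D 3347 and 1850. Families E and F were closer, at 2202.5 and 1978 and at 1218 and 1236.5. In the regressed and differentiating libraries, family C had 873 and 3376.5, family G 802.5 and 722, and family H 3248 and 1627. After thinning to 1000 UMIs, family A had 501.5, 483 and 486 genes per cell, while family B had 328 in the regressed and 215 in the regenerating library, family D 309 and 204, and family E 387 and 203.

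**Figure D3:**
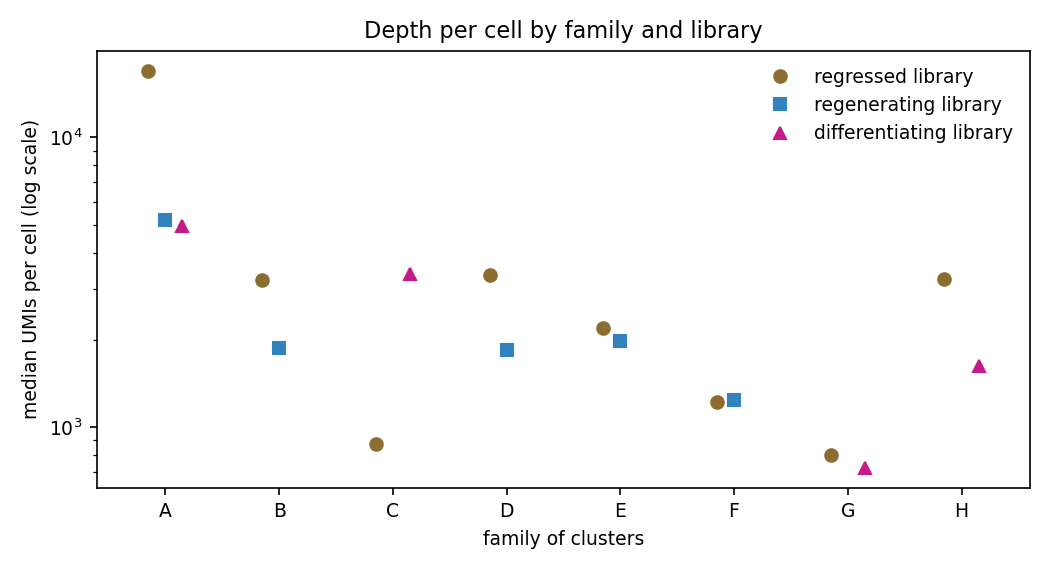
Median UMIs per cell (vertical axis, log scale) of each family of clusters (horizontal axis) in the regressed, regenerating and differentiating libraries, where the library held at least 50 cells of the family. Family A in the regressed library stands at 16997 UMIs against 5182 and 4947.5 in the others.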

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

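The tests on the depth of family A and the draws at 1 level of free RNA were chosen after the results were seen; those on the family C cells of the regressed library and on clusters held by 1 library were set before their results.

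Barcodes removed for having under 200 genes were not empty of signal. The 12 genes that mark cluster 12 (family G) took 54.6% of the UMIs of such barcodes in the regressed library, 15.2% in the regenerating library and 62.4% in the differentiating library. In kept cells outside family G they took 0.255%, 0.275% and 0.118%. Over 30% of UMIs came from these genes in 752 of the 895 regressed barcodes, 259 of the 824 regenerating barcodes and 459 of the 459 differentiating barcodes.

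Median UMIs per cell did not follow family A in every family. Family F had medians of 1236.5 UMIs in the regenerating and 1218 in the regressed library, a ratio of 1.02 where family A had 0.305, but cluster 13 led it in the regressed and cluster 29 in the regenerating library, and inside these the medians were 1180 against 814 and, with 6 regressed cells, 6557 against 1528 UMIs. Family C had a differentiating to regressed ratio of 3.87 where family A had 0.291, and inside cluster 3, which held all regressed cells of family C, the ratio was 2.29. With 1 library per stage these differences were not tested.

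The regressed library held 87 cells of family C, all in cluster 3, whereas the regenerating library held none and family C led the differentiating library. Carry-over of barcodes from the differentiating library is argued against, since 1.15% of these cells (1 of 87) shared a barcode with that library, and 0.253% of the other regressed cells did. Free RNA at 1 level in all regressed droplets is argued against as well. The 193 genes that mark cluster 3 in the differentiating library took 30.6% of the UMIs of these cells. In other regressed cells they took 0.270%, a ratio of 113. In 100 random draws at 1 level in all regressed cells, the 87 cells with the highest shares gave at most 2.11. The genes were chosen to be low in other families and the cells by their cluster, so the size of the ratio is partly set by these choices. Free RNA that varies between droplets was not tested. The median of the 87 cells, 873 UMIs, was below the 2003 of differentiating cells in cluster 3. It stays open whether cells of family C were part of the regressed testis, which was not tested in further fish, or whether cells of another testis entered the suspension before loading, which the design does not separate.

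Clusters held by 1 library made up 88.8% of the 14775 cells when the regressed and regenerating libraries were clustered by themselves. After the median shift per gene over 6 shared clusters was taken off, 77.5% of cells still lay in such clusters. A shift of that size, common to all cells of a library, is argued against as the whole source. The shared clusters are those in which the libraries mixed, so a larger shift in the other clusters was not tested. The shifts of pairs of shared clusters had a median correlation of 0.23 across genes. The difference in UMIs per cell cannot be told apart from other sources. After thinning to 1000 UMIs the share was 60.3%, against 84.1% for the same cells not thinned. The thinned share lies between the bounds of 50% and 70% set for either outcome, and stage and library remain confounded. Thinned cells formed 24 clusters against 28 not thinned, and coarser clusters can mix libraries more whether or not depth differed. The drop therefore does not measure the part of depth.

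Cells of family A in the regressed library had 3.28 times the median UMIs of those in the regenerating library. Deeper sequencing of the regressed library is argued against as the whole source, since 1 factor for all cells would give equal ratios, and the ratio had a median of 1.42 over families B, D, E and F, whose clusters differ between the libraries. Doublets with other regressed cells are argued against too, since the regenerating median of family A plus the highest other regressed median came to 8529 UMIs, below the observed 16997. Inside shared clusters the ratio was 2.76 in cluster 11 of family A, 2.86 in cluster 16 of family D, 2.06 in cluster 22 of family B, and 1.08, 1.17 and 1.21 in clusters 10, 18 and 26, so the gap is neither common to all cells nor particular to family A. A smaller factor common to the library, and a higher RNA content of some cells at the regressed stage, stay open and were not tested in further fish.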

How the results depend on the processing

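Joining at 0.3 or 0.5 and variable-gene profiles were chosen after seeing the data. Shares are compared with the interval of the main share, and spreads with their counting error. With all deposited barcodes, family A had 7.62% of regressed, 49.5% of regenerating and 25.7% of differentiating cells, family B 38.6% of regressed cells and family C 50.7% of differentiating cells. Requiring 1000 UMIs and 500 genes gave 12.4%, 93.0% and 33.6% for family A in that order, 5.83% of regenerating and 0.0467% of differentiating cells for family B, and 0.867% of regressed and 63.5% of differentiating cells for family C; this filter left no cell in family G, whose median cell has 224 genes. With doublets kept, family A had 54.2% of regenerating and 27.4% of differentiating cells, family B 36.9% of regenerating and family C 54.9% of differentiating cells. At resolution 0.5 family A had 50.3% of regenerating cells. With each library clustered alone, family B had 40.8% of regressed and 0.436% of differentiating cells. Joined at 0.5, family A had 1.66% of differentiating cells, and family B had 4.08% of regressed and 36.9% of regenerating cells. Joined at 0.3, family B took in family E and had 62.0% and 40.0%. Resolution 2.0 and variable-gene profiles kept the shares of A, B and C within their intervals. Joins regroup the clusters by construction, and the cause of the other moves was not tested.

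Spreads of log2 ratios follow in the order regenerating against regressed, differentiating against regenerating, differentiating against regressed. They were 0.56, 1.00 and 1.07 with TMM factors, 0.67, 1.05 and 1.14 with the mean of each cell's CPM, 0.95, 1.68 and 1.78 with CPM + 1, 0.49, 0.90 and 0.96 with no minimum of UMIs, 0.54, 1.02 and 1.09 with all barcodes, 0.64, 1.04 and 1.12 with 1000 UMIs and 500 genes, and 0.55 and 1.09 with doublets kept, where the other comparison stayed within counting error. Within family A, TMM factors gave 0.69 for differentiating against regenerating and 0.70 for differentiating against regressed, and clustering each library alone gave 0.37 for regenerating against regressed and 0.71 for differentiating against regressed. The order of the 3 comparisons held in all of these, and the cause of the moves was not tested. CPM + 1 widens ratios of low genes by construction. Log2 ratios of the 4 named genes kept their sign, with ranges of 3.31 to 4.26 for Ssc_10002076, -8.74 to -6.38 for Ssc_10006353, 7.92 to 10.07 for Ssc_10008054 and -6.76 to -5.91 for Ssc_10021848. Of the shares of families D to H under the alternatives, 9 were above and 22 below the interval of the main share and 59 inside it. Thinned to 500 UMIs, genes per cell were 221, 252 and 340, in the order found at 1000. Gene lists and the cell cycle gave no values, and no paired analysis was possible because each stage has 1 library. Depth limits families with few cells, such as the 92 regenerating cells of family E.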

Other observations

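The test of consecutive identifiers was chosen after its result was seen.

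Clusters of families A and C that came mostly from the differentiating library were linked in the neighbour graph, with a weak link between the families. Of the neighbour links of cluster 14, 6.75% went to cluster 8 and 0.679% to cluster 4, and in the reverse direction 0.0342% of the links of cluster 4 went to cluster 14. The profiles of clusters 14 and 4 had a correlation of 0.24. Cluster 24 sent 2.83% of its links to cluster 4 and 2.98% to cluster 20, and cluster 20 sent 3.89% to cluster 3. Along the order 8, 14, 4, 24, 20 and 3, median UMIs per cell were 4234.5, 5951, 3755, 6749, 6866 and 1947. Genes per cell at 1000 UMIs were 482 and 490 in clusters 8 and 14, 688 in cluster 4, and then 649, 589 and 576. The top 50 genes took 40.4% of UMIs in cluster 8, 17.8% in cluster 4 and 26.8% in cluster 3. The order is that of the links and carries no direction or time.

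Genes of cluster 12 were found in a few other clusters. In the regressed library they took 16.7% of UMIs in cluster 26 and 11.4% in cluster 32. In the regenerating library they took 10.7% in cluster 26, 4.41% in the 23 cells of cluster 13 and 3.50% in cluster 25, and in the differentiating library 5.23% in the 32 cells of cluster 25. In the regenerating library the median of the clusters outside 12, 25 and 26 with at least 20 cells was 0.154%. Cluster 25 sent 4.35% of its neighbour links to cluster 12 and 10.4% to cluster 1.

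Genes whose identifiers carry consecutive numbers had like profiles more often than others. Of 5865 such pairs, 2.05% had a correlation above 0.9 across the 32 clusters. In 1000 shufflings of the identifiers the share ran from 0.494% to 1.35%, which argues against chance pairing. Pairs of neighbouring rows in the feature list, which is not in number order, gave 0.815%. The share was 1.55% at a distance of 2, 1.05% at 3, 1.11% at 5, 0.985% at 10 and 0.683% at 20. If the numbers follow gene order along the genome, tandem copies or shared regulation of neighbouring genes may contribute; neither was tested, and reads shared between near-identical copies could give the same pattern.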
